A study of Mus musculus with 6 samples.

How the data were processed

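Values came from 1 deposited isoform table with 6 libraries of mouse neural stem cell cultures, 3 labelled wild type and 3 labelled vimentin knockout. The authors gave FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) for each isoform and library. The deposited coverage columns hold the signal of each isoform as mean reads per base, not scaled to depth. The submitters' processing notes name cutadapt, FastQC, Bowtie2, TopHat2 and StringTie, and their versions are not given there. The wild-type columns carry the letters NT in the table and were matched to the libraries labelled WT by elimination and by number. All value columns were used (0 unused). The genome build is not given in the sources used here. Of the isoforms with Ensembl identifiers also found in GENCODE release M21, 95.9% had identical coordinates, and chromosomes and coordinates are printed as in the table.

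The ratio of coverage to FPKM was constant within each library and gave its aligned bases, equal to 28.9, 31.1 and 36.2 M reads of 150 bases in WT 1 to 3 and 28.4, 30.7 and 32.5 M in KO 1 to 3. A transcript of 2000 bases with 3 reads would have between 0.0414 and 0.0529 FPKM. Between 11660 and 12331 genes had at least 1 FPKM in a library.

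Of 125793 isoforms, 95506 were kept: those of a reference transcript and assembled isoforms that overlap the exons of a named gene. Isoforms that are intergenic, intronic, antisense or run on past a gene were left out. FPKM was summed per gene symbol to 27694 genes, of which 2013 shared an assembled locus with another gene. This definition by class code was chosen after the files were seen. The tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

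Tests used R 4.3.3 with limma 3.58.1, and tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. For genes with a mean FPKM of at least 1 (12080), limma was fitted to log2(FPKM + 1) with a mean-variance trend and 1 coefficient, KO against WT. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes on this scale understate the change of low genes. The same model was used for isoforms (27399), and for isoform shares (22448), the log2 ratio of an isoform to the other isoforms of its gene. Gene lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Gene Ontology terms with 15 to 300 tested genes were tested with camera as well, a test added later than the others. Where a count is given over the list alone, p was adjusted over the tested members of that list.

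Genes were named by rule. The rule named Vim and, in each direction, the 15 called genes with a symbol, other than predicted gene models, that had the largest log2 fold change and whose 3 KO values lay on one side of the 3 WT values. It also named up to 4 called members of each list with the smallest p, or the 2 with the smallest p where none was called, and the 5 called isoforms with the smallest p among genes with a symbol other than predicted gene models. A gene that the rule names is not reported here. Genes named outside the rule were chosen after their values were seen: Hnrnpa0, Eid1, Sox1, Sox2, Sox3, Sox2ot, Aup1, Pank4, Xist and the genes named under other observations.

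The procedure was tested on simulated data with 100 changed features of each size, made from the spread of the real values. At the gene level, 43% of changes of 1 log2 unit and 72% of changes of 2 were recovered, with 9 false calls (7.26% of calls). At the isoform level, 0% and 2% were recovered, and for shares 0% and 0%, with 0 false calls for each. A list shifted by 0.5 was called (1 of 1), with 0 calls among the other lists.

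Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, per-million, median-ratio and quantile scaling, no trend, robust variance, a replicate block, leaving out each library, a minimum fold of 1.5, thresholds of 0.01 and 0.1, reference transcripts only, the highest isoform only, and leaving out mitochondrial, ribosomal and small RNA genes. Added after seeing the data were every class code, sums per assembler locus, array weights, estimated reads with voom, median-ratio scaling without WT 2, and leaving out chromosome 6 genes. Chromosomes were compared after the data were seen, with 10000 random gene sets matched for expression (seed 7). Chromosome 6 was cut into 5 stretches with nearly equal gene numbers. Well expressed genes were those with a mean of at least 10 FPKM in the libraries labelled WT, and 1000 bootstrap draws of genes were made. Called genes within 10 Mb of Vim were counted and tested with Fisher's exact test.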

Results

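RNA was measured in 6 cultures of mouse neural stem cells of the C57/Bl6 strain. These cells divide and can give rise to neurons, astrocytes and oligodendrocytes, and were kept undifferentiated in serum-free medium with the growth factors FGF-2 and EGF. There were 3 cultures labelled wild type (WT) and 3 labelled vimentin knockout (KO), and all were untreated. Ribosomal RNA was removed from total RNA, and strand-specific paired-end libraries were sequenced. The deposited table gave FPKM and mean coverage for 125793 isoforms, of which 46888 had been assembled from the reads. Depth was between 4.26 and 5.43 Gb of aligned bases per library, equal to 28.4 to 36.2 M reads of 150 bases. With 2000 bases of transcript, 3 reads would be worth between 0.0414 and 0.0529 FPKM, so genes at 1 FPKM or above were well covered in each library. The labels do not say whether the cultures came from separate animals, so the p-values below measure the spread between these samples, which may be partly technical.

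Vimentin is the intermediate filament protein that the knockout was meant to remove, and its RNA was the first check of the labels. Vim RNA was higher, not lower, in the libraries labelled KO. The 3 libraries labelled WT had 191, 179 and 186 FPKM (mean 185 ± 6.08 SD, n = 3), and the 3 libraries labelled KO had 650, 732 and 624 FPKM (669 ± 56.1 SD, n = 3), a 3.61-fold difference. The log2 fold change was 1.84 (SE 0.10, adjusted p = 0.0013, limma with Benjamini-Hochberg adjustment), and an exact two-sided permutation test of Vim alone gave p = 0.1, the smallest value that 3 against 3 libraries allow. Vim lies on the plus strand of chromosome 2, from 13573130 to 13582826 in the table. The full-length isoform of 9 exons, ENSMUST00000028062, accounted for 102 ± 43.0 FPKM in the libraries labelled WT and 501 ± 191 FPKM in those labelled KO (SD, n = 3), but did not pass as an isoform (adjusted p = 0.155, limma). An assembled isoform of 10 exons, MSTRG.25773.1, was at 56.9 ± 30.6 FPKM in the libraries labelled WT and 10.1 ± 17.3 FPKM in those labelled KO. A short annotated isoform of 2 exons, ENSMUST00000141365, was listed at 0 in each library labelled WT and at 33.7, 27.2 and 26.0 FPKM in those labelled KO. Because the targeted gene went against the labels, samples are called libraries labelled KO or WT throughout, and each direction below is that of the labels. The table has no exon-level values, so it cannot show what the targeted allele removes.

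**Figure D1:**
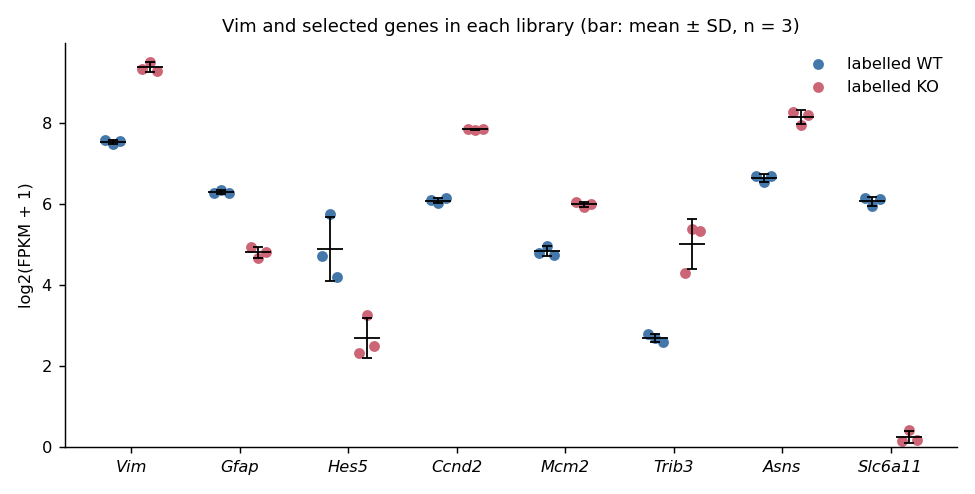
Expression of Vim and 7 other genes as log2(FPKM + 1) (vertical axis) in each library (points; blue, labelled WT; red, labelled KO), with the mean and SD of 3 libraries as black bars. Vim lay above in each library labelled KO (624 to 732 FPKM, against 179 to 191 FPKM), and Gfap, Hes5 and Slc6a11 lay below.

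The main comparison asked how RNA levels differed between cultures labelled KO and cultures labelled WT. With a preset correlation between genes, camera called the lists of DNA replication, mitosis, glycolysis and hypoxia, the integrated stress response and immediate early genes higher in the libraries labelled KO (adjusted p = 0.0818 to 0.13 with an estimated correlation). It called the lists of the Notch pathway, autophagy and lysosome, quiescent neural stem cells, the oligodendrocyte lineage and ribosomal proteins lower (adjusted p = 0.121 to 0.581 with an estimated correlation). In each of the 10 lists most members did not pass. Cyclin D2 (Ccnd2), which drives entry into the cell cycle, rose from 67.1 ± 3.09 to 229 ± 2.47 FPKM, and the amino acid synthesis enzyme Asns rose from 99.2 ± 6.27 to 283 ± 33.2 FPKM. The astrocyte filament gene Gfap fell from 77.8 ± 2.56 to 27.0 ± 2.58 FPKM, and Slc6a11, a GABA transporter of astrocytes, fell from 66.6 ± 5.13 to 0.188 ± 0.127 FPKM (SD, n = 3 for each). In limma on log2(FPKM + 1), 833 of 12080 tested genes passed a Benjamini-Hochberg adjusted p of 0.05, 441 higher and 392 lower in the libraries labelled KO. All 833 had their KO values on one side of their WT values, as a small p from 3 against 3 libraries makes likely. So did 4023 of the tested genes (33.3%, against 10% for a single gene by chance), but genes of the same libraries can move together. Of the called genes, 788 were protein-coding, 130 were more than 2-fold higher and 147 more than 2-fold lower on the log2(FPKM + 1) scale, which understates the change of low genes. The number of called genes fell to 492 without WT 1, 782 without WT 2, 517 without WT 3, 286 without KO 1, 301 without KO 2 and 304 without KO 3. Among the genes named below, the calls of Bst2, Cct4, Hes5, Hmmr, Kif20a, Npc1, Nr4a1, Olig1 and Racgap1 were lost whichever library was left out (highest adjusted p 0.0828 to 0.146, limma). Those of Cat, Cdca8, Dctn1, Fbln2, Fn1, Gbp2, Hist1h3h, Hk2, Kdm6a, Lamp1, Lef1, Lypd1, Map1b, Nbr1, Pdgfra, Srebf1 and Uqcrc2 were lost in 5 of the 6 fits (0.0761 to 0.139).

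Among the 15 named genes with the largest increases, the stress-induced pseudokinase gene Trib3 rose by a log2 fold change of 2.31 (SE 0.31, adjusted p = 0.0139), the cysteine-forming enzyme Cth by 2.26 (SE 0.12, adjusted p = 0.0013), Sesn2 by 2.22 (SE 0.16, adjusted p = 0.0026) and the secreted hormone Stc2 by 1.98 (SE 0.14, adjusted p = 0.00254), all in limma. The membrane metalloprotease Mmp14 rose from 0.066 ± 0.0851 to 5.48 ± 0.846 FPKM, the calcium-binding protein gene S100a1 from 0.20 ± 0.17 to 4.17 ± 0.899 FPKM and the mitochondrial fusion gene Miga1 from 0.448 ± 0.208 to 4.95 ± 0.433 FPKM. Tmem173, which encodes the innate immune adaptor STING, rose from 6.47 ± 0.999 to 27.5 ± 3.60 FPKM. The folate enzyme gene Aldh1l1 rose from 2.77 ± 1.46 to 68.6 ± 0.269 FPKM, and its main isoform, ENSMUST00000032175, went from 0.0521 ± 0.0902 to 40.3 ± 5.33 FPKM (SD, n = 3). Aldh1l1, Dqx1 (log2 fold change 3.31), Pyurf (2.71) and Nqo1 (2.03) share an assembled locus with a neighbouring gene. The Dqx1 value came from transcripts that joined it to Aup1, so it is uncertain. Olig2 (log2 fold change 1.98) was covered here only by long assembled transcripts, which makes its value uncertain too. The 2 remaining genes, the histone gene Hist1h3h and the pseudogene Rps19-ps6, have 1 exon. Hist1h3h was listed at 0, 0 and 18.3 FPKM in the libraries labelled WT and at 256, 247 and 219 FPKM in those labelled KO, and Rps19-ps6 at 0 in all 3 labelled WT and at 22.4, 21.6 and 17.9 FPKM in those labelled KO.

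Among the 15 named genes with the largest decreases, Slc6a11 fell by 5.83 on the log2 scale (SE 0.13, adjusted p = 0.000122, limma), the smallest p of any gene tested. Fbxo32, a ubiquitin ligase subunit of the muscle atrophy program, fell from 21.3 ± 1.70 to 2.87 ± 0.182 FPKM, and the ubiquitin ligase genes Rnf139 and Topors fell from 19.6 ± 0.649 to 1.05 ± 0.341 and from 12.1 ± 1.99 to 1.43 ± 0.558 FPKM. The amino acid transporter Slc38a1 fell from 10.4 ± 0.359 to 1.15 ± 0.0895 FPKM. The RNA-binding protein gene Hnrnph2 went from 34.8 ± 2.95 to 6.11 ± 0.966 FPKM, and the lysosomal protease gene Ctsz from 5.72 ± 1.22 to 0.435 ± 0.105 FPKM. The X-linked gene Xlr3b fell from 23.7 ± 2.86 to 1.53 ± 0.570 FPKM, and the imprinted gene Ndn, which has 1 exon, from 4.97 ± 0.451 to 0.0662 ± 0.0404 FPKM. Pdpn, a surface glycoprotein of glia, fell from 4.56 ± 2.32 to 0.0969 ± 0.0805 FPKM, and Lypd1 from 5.58 ± 2.54 to 0.436 ± 0.0911 FPKM. Cisd3 and Zfp748 fell by 2.34 and 2.25 on the log2 scale. Hes5, a target of Notch signalling, fell from 32.0 ± 18.8 to 5.72 ± 2.46 FPKM (SD, n = 3), and its locus is joined to Pank4 in the assembly. Its values in the libraries labelled WT were 25.5, 53.2 and 17.3 FPKM, and its call was lost whichever library was left out (highest adjusted p = 0.144, limma). The single-exon protocadherin gene Pcdhb11 was listed at 18.6, 14.4 and 16.3 FPKM in the libraries labelled WT and at 0 in each labelled KO. A listed 0 was not proof of absence: of 187 single-exon protein-coding genes, 44 to 63 were listed at exactly 0 in a library labelled WT and 68 to 73 in one labelled KO, against 11 to 27 of 10660 with more exons. Of the 187, 28 were at 0 in every library labelled KO and 4 in every one labelled WT, and 2 were called higher and 10 lower. Calls that rest on such zeros, higher (Hist1h3h, Rps19-ps6) or lower (Pcdhb11), are thus uncertain. Hnrnpa0 and Eid1, which are widely expressed, were at 0 in 1 library each and at 38.7 FPKM or more in the others. Of the 833 called genes, 25 had 1 exon.

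As a group, the genes of chromosome 6 were higher in each library labelled KO. Their median log2 fold change was 0.27 over 604 tested genes, 83 of them called higher and 8 lower, while the medians of the other 18 autosomes lay between -0.09 and 0.08. Against the mean of the libraries labelled WT, the chromosome 6 median was 0.34 in KO 1, 0.33 in KO 2 and 0.31 in KO 3, and against the mean of their 2 companions the libraries labelled WT had 0.00, 0.06 and -0.03. Among the genes named here, Aldh1l1, Dqx1, Pyurf, Asns, Ccnd2, Mcm2, Tpi1, Hk2, Dctn1, Fbln2, Hoxa3 and Rpl32 lie on chromosome 6, as does Slc6a11, which fell. Without chromosome 6 genes, 708 genes were called, 342 higher and 366 lower, and 10 gene lists were called, the same 10 as with them.

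**Figure D2:**
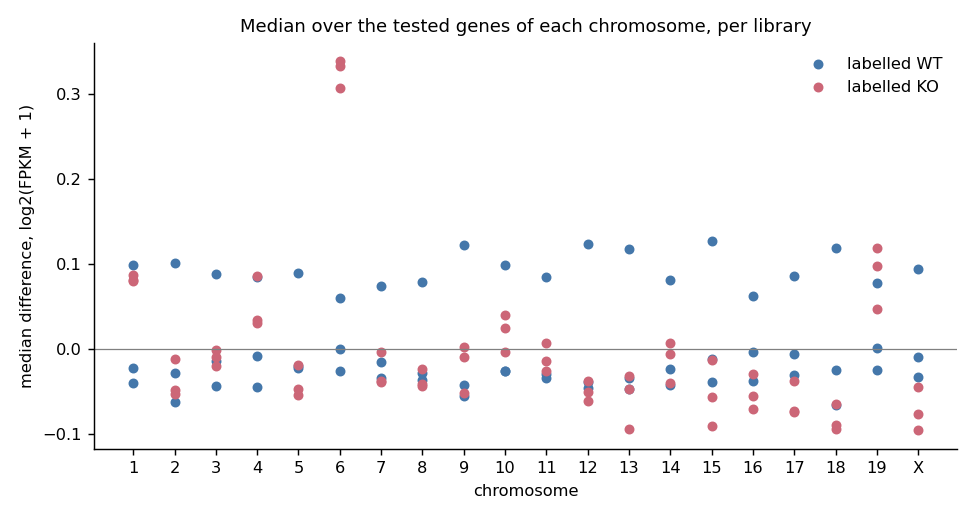
Median difference in log2(FPKM + 1) (vertical axis) over the tested genes of each autosome and of X (horizontal axis), in each library (points; blue, labelled WT; red, labelled KO). Each library labelled KO was compared with the mean of the libraries labelled WT, and each library labelled WT with the mean of the other two, and chromosome 6 lay between 0.31 and 0.34 in the libraries labelled KO.

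In the library WT 2, isoforms in introns, between genes or running on past genes held 16.0% of the FPKM, against 3.75% to 5.27% in the other 5 libraries. Of the bases covered in isoforms, they held 2.94% in WT 2 and 1.21% to 1.55% in the other 5. Across genes, its correlation of log2(FPKM + 1) with WT 1 and WT 3 was 0.865 and 0.863, and that of WT 1 with WT 3 was 0.890. With the libraries labelled KO, WT 1 had correlations of 0.862 to 0.867, WT 2 of 0.831 to 0.838 and WT 3 of 0.871 to 0.881, and those libraries had 0.900 to 0.905 among themselves. Such isoforms were left out of the gene sums, but WT 2 still stood apart there. It had 12331 genes with at least 1 FPKM, against 11660 to 11841 in the other 5 libraries. Without WT 2, 57.3% of called genes were higher in the libraries labelled KO, against 52.9% with it. Whether background reached the gene sums was not tested.

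Of 34 gene lists fixed before the data were examined, 30 had at least 5 tested members, and 10 of these were called by camera with a preset correlation between genes of 0.01, 5 higher and 5 lower in the libraries labelled KO. None of the 10 calls held when the correlation was estimated from the data. The estimate lay below the preset 0.01 for mitosis (-0.0195), the stress response (-0.0114), Notch (-0.0122), the oligodendrocyte lineage (-0.0491) and autophagy and lysosome (0.00501). A higher correlation thus does not account for the loss of these calls. For mitosis, the unadjusted camera p went from 2.52e-08 with the preset to 0.00319 with the lower estimate. The settings therefore differ in more than the value of the correlation. In the other called lists the estimate was 0.0161 to 0.198, and how far it accounts for their loss was not tested. The camera p-values below are Benjamini-Hochberg adjusted over the 30 lists. Fry asks whether the members of a list changed at all, and camera whether they changed more than other genes. A fry call therefore does not back a camera call. Fry called each of the 10 lists but the ribosomal one (fry adjusted p = 0.211). It also called lists that camera did not, among them astrocyte markers (fry adjusted p = 0.000322), extracellular matrix (0.000204) and intermediate filaments (0.00187).

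**Figure D3:**
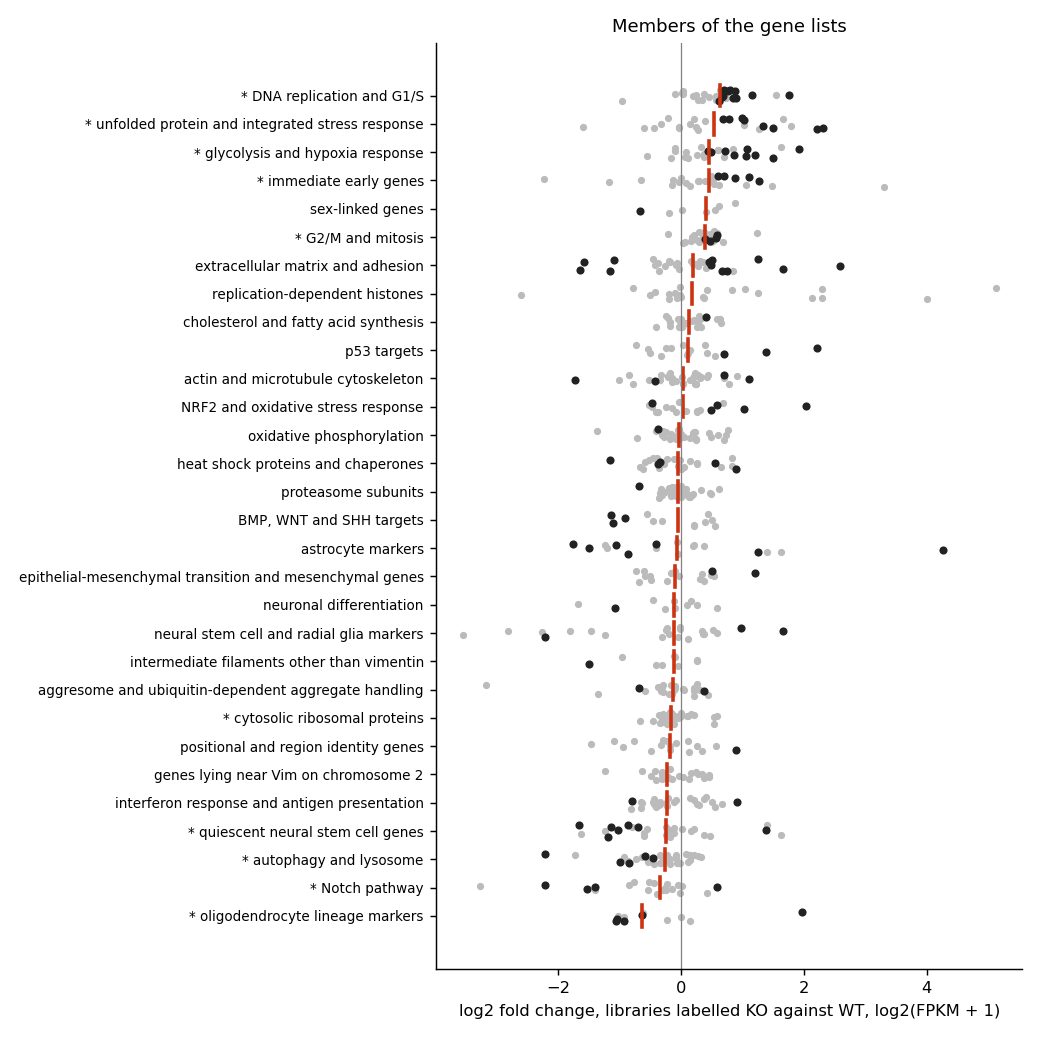
Log2 fold change on the log2(FPKM + 1) scale (horizontal axis) of each tested member of the 30 gene lists tested by camera (rows). Black points passed an adjusted p of 0.05 over all genes, grey points did not, red bars are list medians, and an asterisk marks the 10 lists that camera called with the preset correlation.

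Of 31 tested genes of DNA replication and the G1/S transition, 11 rose, none fell and 20 did not pass, and 21 rose when p was adjusted over the list alone. Beside Ccnd2, the replicative helicase subunit Mcm2 rose from 27.6 ± 2.42 to 62.7 ± 2.71 FPKM, Mcm3 from 26.1 ± 3.69 to 47.8 ± 2.32 FPKM, and cyclin D1 (Ccnd1) from 76.5 ± 3.99 to 144 ± 11.7 FPKM (SD, n = 3). The list had a median log2 fold change of 0.64 (camera adjusted p = 1.36e-10, and adjusted p = 0.0818 with an estimated correlation). Ccnd2 and Mcm2 lie on chromosome 6, and the list was still called without that chromosome (adjusted p = 1.73e-09, camera). For G2/M and mitosis, 4 of 30 rose, none fell and 26 did not pass. When adjusted over the list alone 14 rose, and 29 had a positive fold change. Cdca8 rose from 22.4 ± 2.65 to 33.8 ± 0.790 FPKM and Hmmr, a spindle protein, from 13.3 ± 1.09 to 20.6 ± 1.77 FPKM, and Racgap1 and Kif20a rose by log2 fold changes of 0.40 and 0.48. The calls of Hmmr, Racgap1 and Kif20a were lost whichever library was left out, and that of Cdca8 in 5 of 6 fits (highest adjusted p 0.114 to 0.141, limma). This list had a median of 0.39 (camera adjusted p = 3.78e-07, and adjusted p = 0.0818 with an estimated correlation). The fixed list of replication-dependent histones, which leaves out the called gene Hist1h3h, had no called member among 22 tested, whether adjusted over all genes or over the list alone (camera adjusted p = 0.659). Hist1h2ab, at 0, 0 and 167 FPKM in the libraries labelled WT and 218, 180 and 180 FPKM in those labelled KO, and Hist1h1b, at 4.22 ± 1.66 and 2.04 ± 0.922 FPKM, had the smallest p. Hist1h2ab has 1 exon, and zeros of the kind listed for such genes widen the spread. The lack of calls therefore does not show that histone RNA was unchanged.

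In glycolysis and the hypoxia response, 9 of 26 tested genes were higher, none was lower and 17 did not pass, with 15 higher and 1 lower when adjusted over the list alone. The glycolytic enzyme Tpi1 rose from 168 ± 18.5 to 387 ± 15.9 FPKM and hexokinase 2 (Hk2) from 2.05 ± 0.74 to 7.59 ± 1.52 FPKM, both on chromosome 6. The kinase Pdk1, which holds pyruvate back from oxidation in the mitochondria, rose from 6.80 ± 0.369 to 15.5 ± 1.58 FPKM, and the blood vessel growth factor Vegfa from 8.13 ± 2.72 to 33.1 ± 7.86 FPKM (SD, n = 3). The list median was 0.46 (camera adjusted p = 2.13e-06, and adjusted p = 0.121 with an estimated correlation), and 0.43 without chromosome 6 (adjusted p = 2.74e-06, camera). Oxidative phosphorylation had 1 of 34 genes lower, Uqcrc2 (95.6 ± 3.51 to 73.5 ± 1.73 FPKM), none higher and 33 not passing, with no call when adjusted over the list alone (camera adjusted p = 0.955). Its median was -0.04 and its mean 0.01. In cholesterol and fatty acid synthesis, 1 of 26 genes rose, none fell and 25 did not pass, with the same count over the list alone (camera adjusted p = 0.252). That gene, the lipid regulator Srebf1, rose from 49.7 ± 0.531 to 66.2 ± 2.16 FPKM, but its log2 fold change was -2.10 with the highest isoform only, and it shares its locus with another gene.

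In the unfolded protein and integrated stress response, 8 of 24 tested genes rose, none fell and 16 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Vldlr rose from 20.1 ± 1.16 to 52.5 ± 2.05 FPKM, the cystine transporter Slc7a11 from 6.92 ± 0.0753 to 15.1 ± 0.645 FPKM, and Sesn2 from 6.68 ± 1.44 to 34.4 ± 0.966 FPKM, beside Asns (SD, n = 3). The median log2 fold change was 0.54 (camera adjusted p = 8.28e-05, and adjusted p = 0.0818 with an estimated correlation), and 0.33 without chromosome 6 (adjusted p = 0.000541, camera). Camera with the preset correlation called no other stress or protein-handling list but autophagy and lysosome. Fry also called the NRF2 and oxidative stress list (adjusted p = 0.00497) and the p53 targets (adjusted p = 0.0274). Of 18 NRF2 and oxidative stress genes, 4 rose, 1 fell and 13 did not pass, with the same counts over the list alone (camera adjusted p = 0.401): Hmox1 rose by a log2 fold change of 0.58 and Slc7a11 and Nqo1 rose, while catalase (Cat) fell by 0.46. Among 29 heat shock proteins and chaperones, 2 rose, 3 fell and 24 did not pass, and 4 rose and 7 fell over the list alone (camera adjusted p = 0.518). The constitutive chaperone Hspa8 fell from 689 ± 98.5 to 309 ± 39.5 FPKM and the chaperonin subunit Cct4 from 110 ± 3.85 to 84.8 ± 3.12 FPKM, while mitochondrial Hspa9 rose from 76.8 ± 4.83 to 143 ± 9.14 FPKM and Stip1 by a log2 fold change of 0.56. Of 36 proteasome subunits, 1 fell (Psme4, 35.2 ± 3.70 to 21.5 ± 1.57 FPKM), none rose and 35 did not pass, with the same count over the list alone (camera adjusted p = 0.578). In aggresome and aggregate handling, Nbr1 fell by 0.69 and Dctn1 rose by 0.37 on the log2 scale (but -0.00022 with the highest isoform only), and 22 of 24 did not pass, again with the same counts over the list alone (camera adjusted p = 0.401). Among 16 genes in the list of p53 targets, 3 rose, none fell and 13 did not pass, with 5 higher over the list alone (camera adjusted p = 0.143). The 3 were Sesn2, also in the stress response list, the cell cycle inhibitor Cdkn1a (18.6 ± 2.11 to 50.3 ± 0.759 FPKM) and Trp53 (21.6 ± 0.826 to 35.7 ± 3.65 FPKM). Trp53 encodes p53 itself.

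Of 35 autophagy and lysosome genes, 5 were lower, none was higher and 30 did not pass, and 6 were lower over the list alone. The kinase Ulk1, which starts autophagy, fell from 17.6 ± 1.54 to 9.39 ± 0.90 FPKM, the lysosomal membrane protein gene Lamp1 from 316 ± 78.3 to 154 ± 7.33 FPKM and the cholesterol transporter Npc1 from 63.0 ± 2.78 to 45.8 ± 2.49 FPKM, beside Ctsz (SD, n = 3). The list median was -0.25 (camera adjusted p = 0.00409, and adjusted p = 0.121 with an estimated correlation). The 40 cytosolic ribosomal protein genes were called lower by camera (median -0.16, adjusted p = 0.0336, and adjusted p = 0.581 with an estimated correlation), but no member passed, over all genes or over the list alone. Rpl32, on chromosome 6, was at 170 ± 18.6 and 247 ± 30.3 FPKM and Rpl10 at 225 ± 19.0 and 177 ± 6.82 FPKM in the libraries labelled WT and KO. The ribosomal call was lost without WT 3 (adjusted p = 0.292), without KO 2 (0.0755) and without KO 3 (0.314), under each of 3 scalings (0.0595 to 0.245), with a filter of 5 FPKM (0.0638), without trend (0.052), with the highest isoform only (0.0506) and with every class code (0.101, camera).

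Among immediate early genes, which respond within minutes to growth factors, 5 of 25 rose, none fell and 20 did not pass, and 8 rose and 1 fell over the list alone. Spry4 rose from 19.3 ± 1.57 to 36.1 ± 2.19 FPKM, Egr1 from 27.8 ± 1.06 to 42.8 ± 1.27 FPKM, Fosb from 12.2 ± 1.45 to 31.4 ± 7.44 FPKM and Nr4a1 from 13.2 ± 0.478 to 22.2 ± 3.20 FPKM (SD, n = 3). The median was 0.45 (camera adjusted p = 0.00303, and adjusted p = 0.13 with an estimated correlation). The call of the immediate early genes was lost with reference transcripts only (median 0.28, adjusted p = 0.375) and with the highest isoform only (0.25, adjusted p = 0.26, camera). In the Notch pathway, 3 of 22 genes fell, 1 rose and 18 did not pass, and 5 fell and 1 rose over the list alone. The Notch ligand genes Dll1 and Dll3 fell from 68.8 ± 2.87 to 25.6 ± 0.365 and from 8.01 ± 1.16 to 2.12 ± 0.585 FPKM, as did Hes5, whose call did not outlast leaving out any library, while the ligand gene Jag1 rose from 18.5 ± 0.24 to 28.3 ± 0.654 FPKM. The median was -0.35 (camera adjusted p = 0.00308, and adjusted p = 0.121 with an estimated correlation). Among 12 targets of BMP, WNT and SHH signalling, 3 fell, none rose and 9 did not pass, and 4 fell and 3 rose over the list alone (camera adjusted p = 0.59). Those that fell were the hedgehog receptor Ptch1 (49.8 ± 6.73 to 25.8 ± 0.872 FPKM), the BMP target Id3 (24.8 ± 6.61 to 10.5 ± 0.644 FPKM) and the WNT effector Lef1 (2.28 ± 0.634 to 0.50 ± 0.0979 FPKM).

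Markers of the stem cell state went both ways. Of 22 neural stem cell and radial glia markers, the matrix protein gene Tnc (47.8 ± 2.28 to 154 ± 8.47 FPKM) and the EGF receptor gene Egfr (71.6 ± 12.5 to 141 ± 13.0 FPKM) rose, Hes5 fell (its call was lost whichever library was left out) and 19 did not pass, with the same counts over the list alone (camera adjusted p = 0.967; the median was -0.11 although camera ranked the list up). Sox2, which has 1 exon and was chosen after its values were seen, was listed at 53.3, 0 and 28.4 FPKM in the libraries labelled WT. It was listed at 0 in those labelled KO. Transcripts named for the overlapping Sox2ot held 14.8, 14.2 and 17.0 and then 11.7, 25.7 and 12.2 FPKM. The reads of the whole locus, in units of 1000, were 5.74, 1.56 and 4.76 and then 1.17, 3.56 and 1.83. Of 26 quiescent neural stem cell genes, 6 fell, 1 rose and 19 did not pass, and 8 fell and 1 rose over the list alone. The protease inhibitor gene Cst3 fell from 181 ± 24.2 to 56.6 ± 3.96 FPKM, the BMP receptor gene Bmpr1a from 41.4 ± 2.97 to 19.9 ± 2.42 FPKM (but a log2 fold change of 1.09 with reference transcripts only) and Fgfr3 from 22.1 ± 1.33 to 11.7 ± 1.03 FPKM, while Cdkn1a rose (SD, n = 3). The median was -0.25 (camera adjusted p = 0.0232, and adjusted p = 0.235 with an estimated correlation), and without chromosome 6 it was -0.55 (adjusted p = 0.0175, camera) and without WT 3 -0.40. The quiescence call was lost without KO 3 (adjusted p = 0.0716), with a filter of 5 FPKM (0.0733), with reference transcripts only (0.232) and with the highest isoform only (0.079, camera). Of 11 oligodendrocyte lineage markers, 4 fell, 1 rose (Olig2) and 6 did not pass, with the same counts over the list alone. Cnp fell from 87.9 ± 3.11 to 46.0 ± 2.44 FPKM, Lhfpl3 from 19.0 ± 1.24 to 8.66 ± 0.56 FPKM and Olig1 from 504 ± 37.7 to 326 ± 27.0 FPKM. The median was -0.63 (camera adjusted p = 0.0206, and adjusted p = 0.163 with an estimated correlation), and the call was lost with a filter of 5 FPKM (adjusted p = 0.0638, camera).

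Astrocyte markers did not move together: of 17 tested, 2 rose, 5 fell and 10 did not pass, with the same counts over the list alone (camera adjusted p = 0.40, direction down, median -0.07 and mean 0.05). Aldh1l1, which lies on chromosome 6 and shares its locus, rose. Gfap, the water channel gene Aqp4 (10.9 ± 0.348 to 2.50 ± 0.266 FPKM) and Agt (87.0 ± 4.71 to 41.3 ± 3.04 FPKM) fell. Without chromosome 6 the list had 1 gene higher and 5 lower, with a median of -0.23 (camera adjusted p = 0.163). Gfap was the only called member of 9 tested intermediate filament genes other than Vim, and 8 did not pass; 2 were lower over the list alone (camera adjusted p = 0.187). Of 10 neuronal differentiation genes, 1 fell, Sox4 (385 ± 17.2 to 183 ± 4.11 FPKM), and 9 did not pass, with the same count over the list alone (camera adjusted p = 0.625). Markers of other cells that a culture could hold were low. None of 18 microglia and macrophage markers reached the filter of 1 FPKM. The single endothelial marker tested, Egfl7, was at 1.03 ± 0.536 and 1.91 ± 0.485 FPKM and did not pass. None of the 3 ependymal and ciliated cell markers tested passed; Mlf1 was at 1.10 ± 0.671 and 1.76 ± 0.13 FPKM and Spag6 at 1.43 ± 0.338 and 1.04 ± 0.449 FPKM. Of 4 fibroblast and pericyte markers tested, Pdgfra, also a marker of oligodendrocyte precursors, fell from 7.47 ± 1.66 to 3.03 ± 0.259 FPKM, Fbln2 rose from 2.20 ± 0.666 to 5.22 ± 0.544 FPKM (but a log2 fold change of -0.22 with reference transcripts only), and 2 did not pass; 2 were higher and 1 lower over the list alone. These 4 lists were too small for camera.

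Extracellular matrix and adhesion genes changed in both directions: 8 of 31 rose, 4 fell and 19 did not pass, and 9 rose and 6 fell over the list alone (camera adjusted p = 0.267). Tnc and Mmp14 rose, while the protease inhibitor gene Timp3 fell from 26.0 ± 0.53 to 7.60 ± 0.536 FPKM and Sparc from 152 ± 16.4 to 67.9 ± 1.94 FPKM (SD, n = 3). Among 17 epithelial-mesenchymal transition and mesenchymal genes, Anxa2 (4.88 ± 1.24 to 12.4 ± 0.762 FPKM) and fibronectin (Fn1, 11.5 ± 0.446 to 16.8 ± 0.728 FPKM) rose, none fell and 15 did not pass. Among these 17, 3 rose and 3 fell over the list alone (camera adjusted p = 0.955, ranked up, with a median of -0.10). Of 35 actin and microtubule cytoskeleton genes, 2 rose, 2 fell and 31 did not pass. Over the list alone 3 rose and 3 fell (camera adjusted p = 0.556). The myosin gene Myh9 (26.9 ± 3.49 to 58.9 ± 5.40 FPKM) and Map1b (7.21 ± 0.86 to 12.4 ± 1.25 FPKM) rose, and tau (Mapt, 21.8 ± 1.38 to 5.87 ± 0.478 FPKM) fell. In the interferon response and antigen presentation, Bst2 rose from 0.948 ± 0.0451 to 2.71 ± 0.50 FPKM and Gbp2 fell from 9.88 ± 1.08 to 5.25 ± 0.121 FPKM, and 26 of 28 did not pass, with the same counts over the list alone (camera adjusted p = 0.267). Of 17 positional identity genes, 1 rose, Hoxa3 (6.84 ± 0.109 to 13.7 ± 1.25 FPKM), which shares its locus and lies on chromosome 6, and 16 did not pass; 2 rose over the list alone (camera adjusted p = 0.625). None of 27 tested genes lying near Vim on chromosome 2 passed, over all genes or over the list alone (camera adjusted p = 0.401). Fam107b, at 13.7 and 9.93 FPKM (log2 fold change -0.42, SE 0.10), and Nebl, at 11.2 ± 5.45 and 3.92 ± 0.837 FPKM, had the smallest p. Among 7 sex-linked genes, the X-linked demethylase gene Kdm6a fell from 14.2 ± 0.811 to 8.64 ± 0.692 FPKM, none rose and 6 did not pass. Over the list alone 4 were higher and 2 lower (camera adjusted p = 0.401). Xist lay at or below 0.041 FPKM in each library and Y-linked genes were present in each. The 9 tested genes of the Y chromosome all had a positive fold change, with a median of 0.72, and 1 of them was called.

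At the level of isoforms, 38 of 27399 tested passed an adjusted p of 0.05 in limma, 18 higher and 20 lower in the libraries labelled KO, and belonged to 36 genes, 28 of them called as genes too. Predicted gene models aside, the 5 called isoforms with the smallest p belonged to Slc6a11 (log2 fold change -5.82, adjusted p = 0.00301), Aldh1l1 (5.29, adjusted p = 0.00301), Vim (ENSMUST00000141365, 4.90, adjusted p = 0.00301), Rps19-ps6 (4.43, adjusted p = 0.00368) and Pcdhb11 (-4.12, adjusted p = 0.00532). The isoforms of Rps19-ps6 and Pcdhb11 have 1 exon and that of Vim is short, and each was listed at 0 in every library of a group, so these calls are uncertain. The number of called isoforms was 31 without WT 1, 27 without WT 2, 21 without WT 3, 9 without KO 1, 1 without KO 2 and 14 without KO 3. The share of an isoform in its gene's FPKM was tested for 22448 isoforms, and 0 passed in limma, with 1359 at an unadjusted p under 0.05 and other settings gave 0 to 6 calls. On simulated values, differences of 1 and 2 log2 units were recovered for 43% and 72% of changed genes, but for 0% and 2% of isoforms and 0% and 0% of shares. The low counts for isoforms and shares therefore do not show that isoforms were unchanged.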

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

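The test for a single mislabelled library, the test for exchanged labels and the 3 tests on chromosome 6 were chosen only after the result was seen, and the others before.

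A signal in data outside the gene comparison was an intergenic transcript on the minus strand of chromosome 12 (MSTRG.11532.1, 2 exons, 83188304 to 83211916). It had a mean of 4.90 FPKM in the libraries labelled KO (5.18, 4.64 and 4.87) and 1.54 FPKM in those labelled WT (1.83, 1.09 and 1.71). Of 100 intergenic transcripts with several exons and at least 1 FPKM, it was the 1 that was more than 2-fold higher in each library labelled KO, and 4 were higher in each labelled WT.

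Vim RNA was higher in each library labelled KO. A shift of FPKM between long and short isoforms was excluded as the whole explanation, because the covered bases of Vim, summed over isoforms, were 3.19-fold higher as well. A single mislabelled library was excluded, because the lowest library labelled KO was 3.27 times the highest labelled WT. An exchange of all labels between the groups and a targeted allele that leaves or raises a transcript could not be told apart, since 0 libraries of either group fell within the range of the other and the table has no value that shows the allele.

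WT 2 held more intronic, intergenic and run-on fragments than the other libraries. Unspliced RNA of expressed genes was excluded as the whole explanation, because intronic FPKM was 6.98 times that of the other libraries in genes under 0.1 FPKM, which are nearly silent. Genomic DNA or other genome-wide background fitted, since the excess between genes was 0.707 of that in introns of these genes. No biological explanation was tested.

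Genes of chromosome 6 were higher as a group in the libraries labelled KO. A few strongly changed genes were excluded, because 73.0% of tested chromosome 6 genes had a positive fold change, against 39.5% to 58.7% on other autosomes. A segment that spares 1 or more of 5 stretches was excluded, because their medians (0.24, 0.28, 0.24, 0.37 and 0.35) lay above the median of each other autosome. One covering most of the chromosome, or parts of each stretch, was not excluded, because raising most genes of a stretch lifts its median. Whether the 5 medians differed beyond their spread was not tested. An extra copy of chromosome 6 in part of the cells labelled KO fitted. Well expressed genes were 0.37 log2 units higher relative to the other autosomes, and 0.335 to 0.406 in the single libraries labelled KO. These values lay under the 0.58 of 3 copies against 2. The 0.37 would correspond to 57.6% of cells if expression followed copy number. Its bootstrap SE of 0.026 came from drawing genes and leaves out the spread between cultures. A lost copy in part of the cells labelled WT would raise the same ratio (up to 1 for 2 copies against 1) and was not tested, DNA was not analysed here, and a link with the genotype was not tested.

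Other splits of the 6 libraries into 3 and 3 were tested for each count. The real split gave 833 genes, 38 isoforms, 0 shares and 10 lists, and the highest of the other splits gave 10, 7, 1 and 5. With 10 splits the share of splits with at least as many calls (1 of 10, 1 of 10, 10 of 10 and 1 of 10) cannot fall under 0.05.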

How the results depend on the processing

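The direction of Vim was kept under each alternative, with log2 fold changes from 1.66 (voom) to 2.38 (reference transcripts only), and from 1.78 to 1.89 when 1 library was left out. It missed the threshold with the highest isoform only (2.28, adjusted p = 0.0947). The replicate block left Vim at 1.84 (adjusted p = 0.0551) and gave 15 genes and 0 isoforms. Deviations from the group mean had correlations of 0.0119, -0.0031 and 0.065 in pairs with the same number, and -0.0447 to 0.0332 in other pairs. Such values cannot show whether cultures of one number shared an animal or a day, which the labels do not give. The count of genes was 68 with a minimum fold of 1.5, 219 at an adjusted p under 0.01, 1600 under 0.1, 235 with reference transcripts only, 128 with the highest isoform only and 542 with every class code, and 286 to 782 when 1 library was left out. Isoforms numbered 14 without a filter, 75 with a filter of 5, 22 without trend, 66 with robust variance, 83 with array weights, and 1 to 31 when 1 library was left out. Shares numbered 3 with a pseudocount of 0.1, 6 without a filter, 2 with a filter of 5, 3 with per-million scaling, 1 with quantile scaling, 4 without trend, 5 with array weights, and 0 to 3 when 1 library was left out. Lists numbered 0 with an estimated correlation, 17 with fry, 7 with a filter of 5 FPKM, 7 with the highest isoform only, 8 with reference transcripts only, and 8 to 10 when 1 library was left out (with an estimated correlation each call was lost, and with the filter, the isoform settings or a library left out those of the quiescence, oligodendrocyte, ribosomal or immediate early lists). Named genes that reversed were Bmpr1a (1.09) and Fbln2 (-0.22) with reference transcripts only, and Dctn1 (-0.00022) and Srebf1 (-2.10) with the highest isoform only. Leaving out a library leaves fewer samples, a stricter threshold or minimum fold passes fewer genes, and for the rest the cause was not tested. Every class code, array weights and voom were chosen after seeing the data. Of 97 called named genes, 54 to 81 stayed called when 1 library was left out, and 11 with the replicate block. With the highest isoform only, 41 of 96 stayed called, and with reference transcripts only 50 of 94. Depth limits genes near the floor of 0.0414 to 0.0529 FPKM.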

Other observations

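The test for called genes near Vim was chosen before the result was seen, and the Gene Ontology genes and chromosome Y below were chosen only after.

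Among 1004 Gene Ontology terms, camera called 16, 12 higher and 4 lower in the libraries labelled KO, and 0 with an estimated correlation (adjusted p = 0.99). The 33 genes that charge transfer RNA with amino acids included 9 called higher and none lower, among them Eprs, Gars, Iars and Lars (camera adjusted p = 0.00991 over the terms). Of 23 genes of amino acid biosynthesis, 7 were higher and none lower, among them Cth, Asns and Aldh18a1 (camera adjusted p = 0.0362), and of 20 genes of one-carbon metabolism 7 were higher and 1 lower, among them Aldh1l1 and Mthfd2 (camera adjusted p = 0.029). Of 54 nuclear pore genes, 6 were higher and 1 lower (camera adjusted p = 0.0362). Of 92 endosome membrane genes and 76 late endosome genes, 8 and 7 were lower, with Lamp1 in both, and none was higher (camera adjusted p = 0.0362 and 0.0385).

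The 9 tested genes of chromosome Y had medians of 0.65, 0.73 and 0.73 in KO 1 to 3 against the mean of the libraries labelled WT, and of 0.24, -0.18 and -0.05 in WT 1 to 3 against the other 2.

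A hypothesis was that sequence flanking the targeted allele changes genes around Vim. Within 10 Mb of Vim, 3 of 61 tested genes were called (Prkcq, Gm13292 and Mcm10; 4.92%, exact 95% interval 1.03% to 13.7%), against 829 of 12018 elsewhere (6.90%). A one-sided Fisher's exact test gave p = 0.801, so an excess and no excess cannot be told apart at this number of genes.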
